A study of Mus musculus with 20 samples.

How the data were processed

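Ventral prostates were taken from WT and ARNoC/Y males that had been orchidectomised and then given vehicle or testosterone for 4 days, and total RNA of snap-frozen tissue went into Illumina TruSeq libraries. The table of 20 libraries gave 4 groups of 5. The authors' notes name FastQC 0.11.7, HISAT2, SAMtools 1.5, HTSeq and DESeq2 and the mouse build mm10. The annotation, the strand setting and any read filter are not given in the sources used here.

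The deposited count table holds raw counts per gene symbol for 43472 genes, for which the authors' notes name an aligner (HISAT2) and a read counter (HTSeq) without giving their settings. The deposited signal values are normalized counts, the count divided by the size factor of its library, for 23221 genes whose counts sum to 4 or more. The deposited ratio values are the DESeq2 size factors of the libraries, each a median of ratios to the geometric mean of a gene. Each normalized value times its size factor gave the count back within 4.2e-09, and 100% of the products were whole within 1e-06. Each of the sample columns was matched to its label, with 0 left over. Replicate numbers follow the order of the labels and pair nothing. Coordinates were taken from GENCODE M21, which uses the same build as the authors. By symbol 39449 of the counted genes matched, and by a synonym 928, and 98.3% of the genes tested have coordinates.

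Genes with at least 10 normalized counts in at least 5 of the 20 libraries were tested, which left 15261. Counts were scaled with trimmed means of M-values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3, with 1 mean per group and the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The common biological coefficient of variation was 0.214. The 5 comparisons were testosterone against vehicle in WT and in ARNoC, ARNoC against WT with vehicle and with testosterone, and the interaction, which is the ARNoC response minus the WT response. The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. That plan had assumed normalized values alone and named limma-trend on log2 of the normalized count plus 1. Since raw counts were present, edgeR became the main test and limma-trend (limma 3.58.1) an alternative. Intervals of the interaction and the list tests stayed on the limma scale. Fold changes are ratios, and limits of genes with no count in a group use a floor of 3 counts over the group. Intervals from counts cover counting error alone.

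Genes were named by a rule. It took fixed genes in every comparison, among them Fkbp5, Pbsn, Odc1, Mki67 and Clu. Some genes that the rule takes are not reported here. For each testosterone response it took the 6 largest rises and the 6 largest falls with a mean of at least 50 normalized counts in the higher group and no overlap between libraries. For each genotype comparison it took the 6 largest differences each way, with a mean of at least 50 in the higher group of the pair. For each list called in WT it took the 2 members with the smallest adjusted p in the direction of the list. The Hoxa genes, Hoxa11os, 5730457N03Rik, Evx1, Gm27817, Gm27454, Surf6, Med22, Sbp, Mat2a, Srm, Amd1, Sat1, B2m, H2-K1, H2-D1, Cyp2b10 and P2rx6 were chosen after their values were seen.

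In all 34 gene lists were written down, of pathways, androgen and glucocorticoid responses and cell-type markers, and the 33 with at least 5 tested members were tested. The seminal vesicle list had 1 tested member of 11 and was not tested. Lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Adjusted p from camera covers the 33 lists of a comparison. Camera works on the limma scale, while list medians are those of edgeR's log2 values unless stated. Marker scores are the mean log2 value of the markers of a list in a library. Differences in scores and in library makeup were tested with exact permutation tests of 5 against 5 libraries, two-sided, for which the smallest p is 0.00794.

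The alternatives were limma-trend with other pseudocounts, limma-voom, array weights, a robust fit, DESeq2 1.42.0, other scalings and filters, a 2-fold threshold, a fit of the compared groups alone and leaving out each library in turn. Chosen after the data were seen were limma-trend as first planned, the deposited size factors, leaving out both stroma-poor vehicle libraries, the stromal score as a covariate, and fry. On simulated data the test recovered 85% of 40 genes with a log2 change of 1 in WT, 73.3% of 30 in the vehicle genotype comparison and 66.7% of 30 in the interaction. The changed genes were drawn from those with a mean of at least 50 counts, so these shares do not cover tested genes of fewer counts. Many genes were changed at once, which loosens the adjusted threshold, so a few isolated changes may be recovered less often. Figures were drawn with matplotlib 3.10.9. Read alignment was not repeated, and differential exon use and sequence variants were not analysed here.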

Results

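Gene expression was measured by bulk RNA sequencing in the ventral prostate of orchidectomised male mice that received vehicle or testosterone for 4 days. Wild type C57BL/6J males (WT) were set beside ARNoC/Y males (ARNoC), which carry an altered androgen receptor whose amino-terminal and carboxyl-terminal regions no longer interact. Each of the 4 groups held 5 libraries: WT with vehicle, WT with testosterone, ARNoC with vehicle and ARNoC with testosterone. The design asks how the prostate responds to the return of androgen and whether that response needs the interaction within the receptor. Libraries held 8861646 to 21600352 counts, and 15261 genes passed the filter on low values. Values are normalized counts as mean ± SD over 5 libraries, and coordinates are those of the mouse build mm10. No label states that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries. Replicates differed by more than sampling noise in all 40 pairs within groups (chi-square per degree of freedom 7.97 to 42.9, where noise gives 1), so each counted once. The altered sequence of ARNoC mice cannot be seen in gene counts, so the genotype labels were not checked.

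Testosterone in WT prostates raised genes of secretion, protein folding in the endoplasmic reticulum and cholesterol synthesis, and lowered markers of macrophages and lymphocytes. Spink3, which encodes a secreted protease inhibitor (chromosome 18, 43728082 to 43737557), rose 224-fold from 3688 ± 1475 to 823300 ± 212200. Car2, which encodes a carbonic anhydrase (chromosome 3, 14886273 to 14900770), fell 51.7-fold from 19230 ± 4246 to 369.9 ± 94.96. Of the 15261 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5985, of which 3114 rose and 2871 fell. At least a 2-fold change was seen in 769 of the genes that rose and 1046 of those that fell. The 10 libraries showed no overlap between the groups in 3968 called genes, where chance gives 0.794% of genes.

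Known androgen-induced genes stood among those that rose in WT. Fkbp5, a co-chaperone of steroid receptors, rose 5.50-fold (log2 2.46 ± 0.11 SE, adjusted p 3.02e-12). Pbsn, the secreted protein probasin, rose 8.39-fold, with a wide spread between libraries (1432 ± 1134 to 11950 ± 10900), or 5.19-fold without WT testosterone library 5. Odc1, the first enzyme of polyamine synthesis, rose 4.90-fold from 336 ± 52.7 to 1644 ± 88.6. Clu, or clusterin, a gene known to be high in the regressed prostate, fell 1.96-fold from 8240 ± 1476 to 4182 ± 613. The proliferation marker Mki67 was at 91.9 ± 38.4 with vehicle and 237 ± 206 with testosterone and did not pass the test (log2 1.37, adjusted p 0.105), except with the stromal covariate (1.76). The genes with the largest rises also included Abo, a glycosyltransferase gene of blood group antigens (68.4-fold), and the long noncoding RNA D030018L15Rik (106-fold). Mroh4 and Scgb2b4-ps had no count in any WT vehicle library and rose at least 127-fold and at least 93.1-fold, against a floor of 3 counts over the group. Syt10, a synaptotagmin gene with 3 counts over that group, rose 122-fold, with a 95% counting interval of 41.8 to 592. Among the other large falls were those of the chemokine genes Cxcl5 (47.9-fold) and Cxcl15 (31.2-fold), the vesicle-priming gene Cadps (39.2-fold), Clca2 (33.1-fold) and the ectonucleotidase gene Entpd8 (25.7-fold). Without WT testosterone library 5 the falls of Cxcl5 and Clca2 were 136-fold and 94.8-fold, and without WT vehicle library 1 that of Cadps was 21.9-fold. Reads of Scgb2b4-ps, Scgb2b7, Sbp and Sbpl, and of H2-Q10 and Gm12873, can be shared with similar family members, so these values are uncertain.

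**Figure D1:**
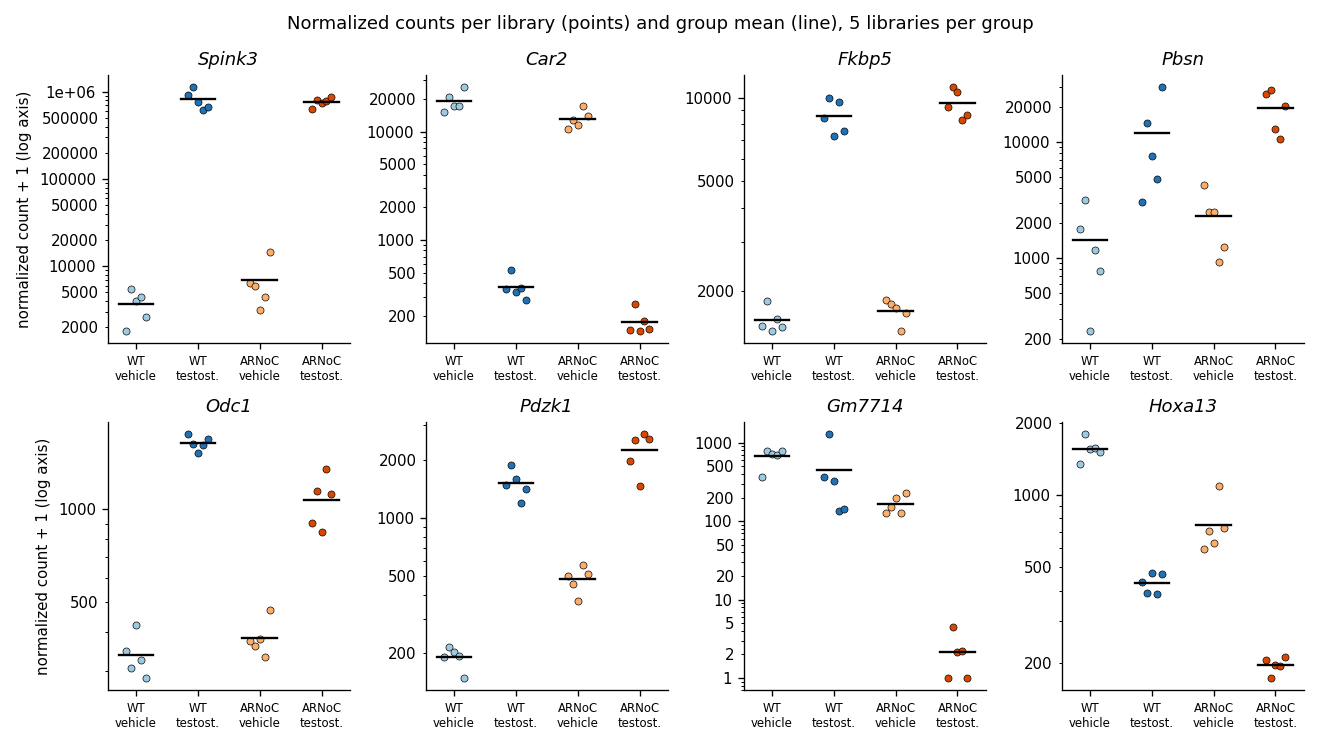
Normalized counts plus 1 on a log axis for 8 genes in the 4 groups, with 1 point per library and a line at each group mean. Spink3, Fkbp5 and Odc1 rose with testosterone in both genotypes while Car2 fell, and Hoxa13 was lower in ARNoC than in WT with vehicle (752 against 1555 on average) and with testosterone (195 against 430).

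Secretory genes and the export pathway rose together in WT. Among 19 measured secretory products of the mouse prostate, 14 rose and 0 fell, with the same counts adjusted over the list alone. Among these was the metalloproteinase inhibitor gene Timp4, at 9.20-fold. The list had a median log2 change of 1.76 (camera adjusted p 5.47e-09, and adjusted p = 0.202 with an estimated correlation). Of 51 genes of folding and export in the endoplasmic reticulum, 50 rose, and 51 rose adjusted over the list alone. The chaperone gene Calr rose 4.00-fold and the cargo receptor gene Lman1 2.28-fold, and the list median was 1.04 (camera adjusted p 1.08e-28, and adjusted p = 0.293 with an estimated correlation). Of 76 androgen-responsive genes fixed in advance, 37 rose and 19 fell, or 37 and 21 adjusted over the list alone. The transcription factor gene Zbtb16 rose 5.08-fold. The list median of 0.30 (camera adjusted p 0.00117, and adjusted p = 0.293 with an estimated correlation) turned to -0.12 under total-count scaling.

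Several metabolic groups rose in WT as well. In cholesterol synthesis 15 of 24 genes rose and 2 fell, all-gene and adjusted over the list alone, with the sterol reductase genes Tm7sf2 at 3.13-fold and Dhcr7 at 1.86-fold (camera adjusted p 4.73e-05, and adjusted p = 0.359 with an estimated correlation). In the integrated stress response list 11 of 24 genes rose and 2 fell, also adjusted over the list alone. Its examples were the serine and folate enzyme genes Mthfd2 (7.14-fold) and Phgdh (3.02-fold), and its median of 0.40 turned to -0.02 under total-count scaling (camera adjusted p 0.00122, and adjusted p = 0.359 with an estimated correlation). In zinc and citrate handling 11 of 23 genes rose and 3 fell, or 12 and 4 adjusted over the list alone. The transporter genes Slc30a10 (17.5-fold) and Slc39a11 (2.10-fold) rose, and the median of 0.41 turned to -0.02 under total-count scaling (camera adjusted p 0.0107, and adjusted p = 0.359 with an estimated correlation). Polyamine genes went both ways, with 5 of 14 up and 4 down, or 5 and 5 adjusted over the list alone, and the list was not called (camera adjusted p 0.412). Named here after their values were seen, Mat2a, Srm and Amd1, which with Odc1 make polyamines and their precursor, rose by log2 3.32, 1.48 and 1.15. Sat1, which acetylates polyamines for breakdown and export, fell by 1.51 on the log2 scale.

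Markers of immune cells fell in WT. All 24 macrophage and myeloid markers fell, also adjusted over the list alone, with a median log2 change of -2.07 (camera adjusted p 1.94e-09, and adjusted p = 0.359 with an estimated correlation). Aif1 fell 4.39-fold and Ctss, cathepsin S, 3.77-fold. Of 15 lymphocyte markers 9 fell and 0 rose, or 10 and 0 adjusted over the list alone, among them Cd3g at 2.55-fold and Nkg7 at 2.47-fold (median -1.45, camera adjusted p 0.000156, and adjusted p = 0.359 with an estimated correlation). Genes linked to regression fell in 14 of 30 cases and rose in 2, also adjusted over the list alone, with Gas6 at 2.78-fold lower (camera adjusted p 0.00652, and adjusted p = 0.359 with an estimated correlation). Of 13 basal epithelial markers 8 fell and 1 rose, also adjusted over the list alone, with the keratin genes Krt17 at 2.75-fold and Krt14 at 2.65-fold lower (camera adjusted p 0.0255, and adjusted p = 0.531 with an estimated correlation). Fibroblast and matrix markers fell in 11 of 30 cases and rose in 2, or 17 and 2 adjusted over the list alone, with Lum at 8.02-fold and Fn1 at 4.12-fold lower (camera adjusted p 0.0109, and adjusted p = 0.805 with an estimated correlation). The call of Lum ended with limma-voom (log2 -3.02), and its fall was 15.4-fold without WT testosterone library 5. Endothelial markers fell in 5 of 22 cases, or 2 adjusted over the list alone, with Robo4 at 2.59-fold and Egfl7 at 1.75-fold lower (camera adjusted p 0.00498, and adjusted p = 0.805 with an estimated correlation). Of 13 adipocyte markers 1, the lipase gene Lipe, fell, at 2-fold, all-gene and adjusted over the list alone (camera adjusted p 0.0255, and adjusted p = 0.805 with an estimated correlation). The fibroblast call ended without WT vehicle library 5 or WT testosterone library 2 (camera adjusted p 0.0554 and 0.0779), and the adipocyte call without WT vehicle library 1 or WT testosterone library 2 or 3 (0.0734, 0.0989 and 0.105).

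The stromal and immune lists moved with libraries that stood apart. WT vehicle library 2 and ARNoC vehicle library 5 had the lowest stromal marker scores of the vehicle groups (8.44 and 7.79) and the lowest myeloid scores (6.97 and 6.48). Without both libraries, 6223 genes were called in WT and 5551 in ARNoC. The lowest stromal score of all libraries was that of WT testosterone library 2 (7.55), which stayed in this setting. Scaling to the total count moved the median of all genes by -0.42 in WT and -0.35 in ARNoC, so changes are relative to the median gene. It gave 1099 genes up and 9105 down in WT and 1178 up and 7538 down in ARNoC. The 10 most abundant genes took 7.99 to 9.56% of the counts in WT with vehicle and 21.4 to 28.1% with testosterone.

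The remaining lists were not called in WT. Up and down counts were 10 and 3 of 40 S phase genes (8 and 3 adjusted over the list alone), 3 and 0 of 38 G2 and mitosis genes (2 and 0), 4 and 2 of 22 fatty acid synthesis genes and 3 and 5 of 41 ribosome biogenesis genes (2 and 5). They were 0 and 2 of 47 cytosolic ribosomal proteins (0 and 1), 10 and 1 of 45 oxidative phosphorylation genes (9 and 1), 9 and 4 of 24 glucocorticoid-responsive genes and 8 and 7 of 29 nuclear receptors and cofactors (8 and 8). They were 1 and 4 of 14 androgen metabolism genes, 4 and 8 of 16 proximal luminal markers, 3 and 8 of 16 luminal markers (3 and 9) and 2 and 0 of 20 smooth muscle markers (0 and 0). They were 5 and 13 of 35 interferon and MHC genes, 1 and 7 of 22 immediate-early genes, 4 and 8 of 32 stromal growth factors and 1 and 2 of 5 urothelium markers. They were 0 and 0 of 19 skeletal muscle markers, 0 and 1 of 10 nerve markers and 0 and 1 of 5 erythroid markers (0 and 0). Counts in brackets are adjusted over the list alone where they differ. Camera adjusted p for these lists lay at 0.0931 or above.

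Testosterone in ARNoC prostates also raised Spink3, Abo, Fkbp5, Pbsn and Odc1 and lowered Car2, Cxcl5 and Clu, while some named genes went apart. Spink3 rose 112-fold from 6862 ± 4424 to 767300 ± 88430, and Abo 47.1-fold from 580.8 ± 141 to 27300 ± 4477. Fkbp5 rose 5.65-fold from 1693 ± 164 to 9529 ± 1145, and Pbsn 8.60-fold from 2285 ± 1315 to 19610 ± 7681. Odc1 rose 2.81-fold from 383.5 ± 52.8 to 1073 ± 203. Car2 fell 75.3-fold from 13190 ± 2647 to 174 ± 47.4, Cxcl5 171-fold and Clu 2.35-fold. Gm7714 fell 129-fold (209-fold without ARNoC testosterone library 2) and was not called in WT (log2 -0.57), and Scgb2b7, which rose 34.2-fold in WT, was not called in ARNoC (2.04-fold); their interactions of -6.45 and -4.07 did not pass edgeR's test (adjusted p 0.0666 and 0.394). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 5528 genes were called, of which 2963 rose and 2565 fell, with 778 and 661 of these changed at least 2-fold. Mki67 rose 3.71-fold (adjusted p 0.0274), but without ARNoC testosterone library 4 the log2 change was 1.19 and the call ended, as it did without ARNoC testosterone library 3 (1.67) or ARNoC vehicle library 2 (1.79), 3 (1.78) or 5 (1.69). It also ended with limma-trend (1.47, or 1.43 with a pseudocount of 5), limma-voom (1.68), array weights (1.2), total-count scaling (1.54) and without both stroma-poor libraries (1.69). Among the genes with the largest rises were C2cd4a (56.0-fold), the calcium channel gene Cacna1i (69.6-fold, or 121-fold without ARNoC vehicle library 1) and G6pc2 (97.8-fold, with counts in ARNoC vehicle library 1 alone of that group). Mroh4, with 3 counts in 1 ARNoC vehicle library, rose 176-fold (95% counting interval 60.2 to 854). Adam7, with 2 counts in 1 vehicle library, was 2410-fold higher (counting interval 667 to 19900), with 2649 in ARNoC testosterone library 3 and 140 to 534 in the others. Without that library its fitted log2 rise was 9.35 in place of 10.78. Fitted log2 rises without the only vehicle library that had counts were 12.61 for Adam7 (library 1), 9.22 for G6pc2 (library 1) and 9.41 for Mroh4 (library 2), values that depend on the prior count. Scgb2b4-ps had no count with vehicle and rose at least 10.3-fold.

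Genes of secretion and protein export rose in ARNoC, and those of the cell cycle were higher in some testosterone libraries of ARNoC and of WT. Secretory products rose in 16 of 19 cases and fell in 0, or 17 and 0 adjusted over the list alone (camera adjusted p 2.47e-10, and adjusted p = 0.115 with an estimated correlation). Genes of the endoplasmic reticulum rose in 48 of 51 cases, also adjusted over the list alone, with Calr at 3.63-fold (camera adjusted p 2.55e-25, and adjusted p = 0.177 with an estimated correlation). Androgen-responsive genes rose in 36 of 76 cases and fell in 11, or 39 and 13 adjusted over the list alone. Their median of 0.32 (camera adjusted p 0.00013, and adjusted p = 0.138 with an estimated correlation) turned to -0.03 under total-count scaling. Glucocorticoid-responsive genes rose in 10 of 24 cases and fell in 3, or 10 and 4 adjusted over the list alone (camera adjusted p 0.00513, and adjusted p = 0.138 with an estimated correlation). S phase genes rose in 18 of 40 cases and fell in 2, or 19 and 2 adjusted over the list alone (camera adjusted p 0.00219, and adjusted p = 0.76 with an estimated correlation). G2 and mitosis genes rose in 19 of 38 cases and fell in 0, or 32 and 0 adjusted over the list alone (camera adjusted p 0.000643, and adjusted p = 0.76 with an estimated correlation). G2 and mitosis scores of ARNoC testosterone libraries 1 and 5 (4.88 and 4.52) lay within the vehicle range of 3.93 to 5.42, as did their S phase scores (6.25 and 6.12, vehicle 5.80 to 6.25), while libraries 2, 3 and 4 had mitosis scores of 5.71 to 7.1. In WT, where neither list was called, testosterone libraries 3 and 4 had mitosis scores of 6.46 and 5.88, above the WT vehicle range of 4.09 to 5.34. Their S phase scores of 6.95 and 6.73 also lay above that of WT vehicle (5.99 to 6.23). WT testosterone libraries 1, 2 and 5 had mitosis scores within the WT vehicle range. Smooth muscle markers rose in 8 of 20 cases, also adjusted over the list alone (camera adjusted p 0.0234, and adjusted p = 0.845 with an estimated correlation). That call ended without ARNoC vehicle library 2 or 5 or ARNoC testosterone library 1 or 3 (0.0556 to 0.119).

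Several metabolic lists rose in ARNoC and immune markers fell. Cholesterol synthesis genes rose in 21 of 24 cases and fell in 1, also adjusted over the list alone (camera adjusted p 8.49e-09, and adjusted p = 0.177 with an estimated correlation). Stress response genes rose in 13 of 24 cases and fell in 1, or 13 and 2 adjusted over the list alone, with Mthfd2 at 8.75-fold (camera adjusted p 0.000501, and adjusted p = 0.366 with an estimated correlation). Zinc and citrate genes rose in 16 of 23 cases and fell in 3, or 16 and 4 adjusted over the list alone (camera adjusted p 0.00176, and adjusted p = 0.18 with an estimated correlation). Oxidative phosphorylation genes rose in 15 of 45 cases and fell in 1, also adjusted over the list alone. Their median of 0.14 turned to -0.20 under total-count scaling (camera adjusted p 0.000919, and adjusted p = 0.76 with an estimated correlation). Fatty acid synthesis (5 up and 2 down of 22) and polyamine genes (6 and 3 of 14), with the same counts adjusted over the list alone, were not called as lists (camera adjusted p 0.272 for each). Myeloid markers fell in 18 of 24 cases, or 19 adjusted over the list alone, with a median of -1.20 (camera adjusted p 4.86e-05, and adjusted p = 0.631 with an estimated correlation). Lymphocyte markers fell in 8 of 15 cases, also adjusted over the list alone (camera adjusted p 0.00357, and adjusted p = 0.413 with an estimated correlation). Basal markers fell in 7 of 13 cases, also adjusted over the list alone (camera adjusted p 0.0455, and adjusted p = 0.631 with an estimated correlation), a call that ended without ARNoC vehicle library 2, 4 or 5 or ARNoC testosterone library 1, 2 or 5 (0.0507 to 0.099). Urothelium markers fell in 2 of 5 cases, or 3 adjusted over the list alone (camera adjusted p 0.0217, and adjusted p = 0.413 with an estimated correlation), a call that ended without ARNoC vehicle library 5 (0.0514). Regression genes fell in 10 of 30 cases and rose in 4, or 11 and 5 adjusted over the list alone, and the list was not called (camera adjusted p 0.189). Fibroblast markers fell in 1 of 30 cases, also adjusted over the list alone, and endothelial and adipocyte markers in 0 of 22 and 0 of 13 (camera adjusted p 0.639, 0.734 and 0.722).

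**Figure D2:**
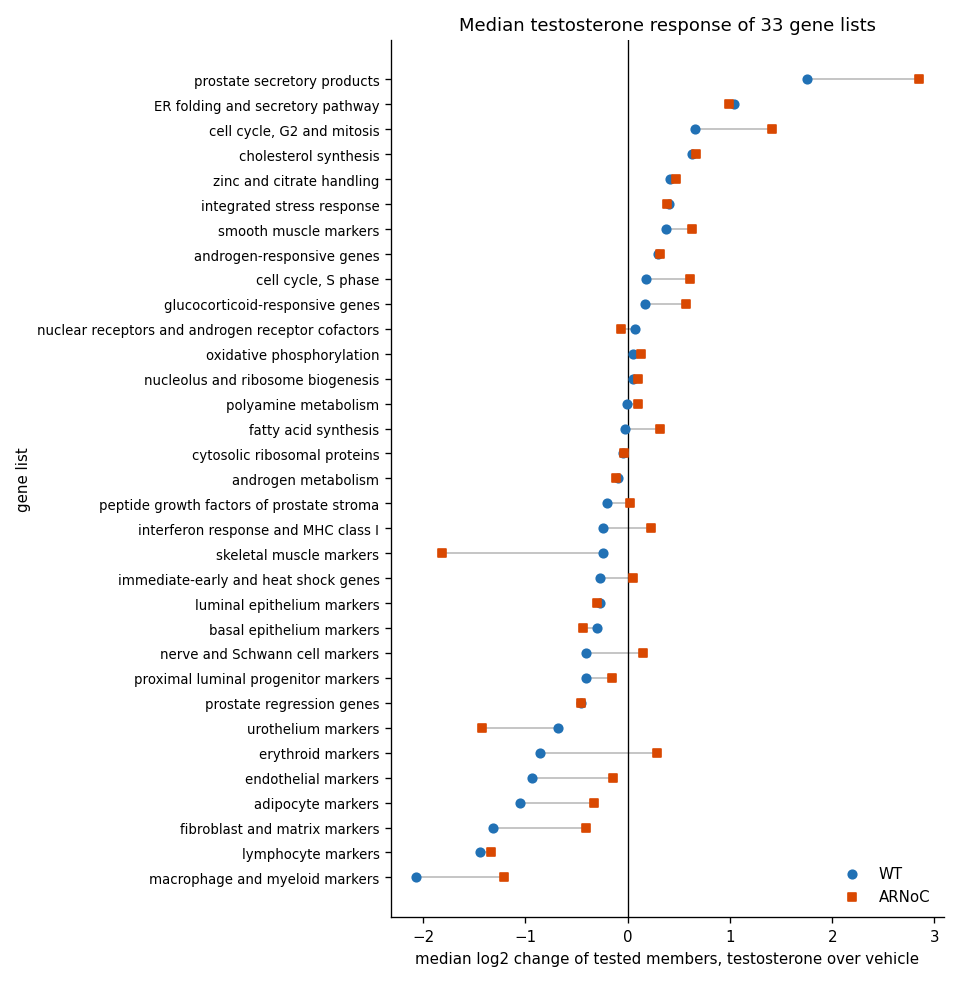
Median log2 fold change of the tested members of 33 gene lists for testosterone against vehicle in WT and in ARNoC, 1 point per list and genotype. Secretory products lie at 1.76 and 2.85 and myeloid markers at -2.07 and -1.20; medians of the androgen-responsive, stress response and zinc lists change sign in WT under total-count scaling.

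The responses of the 2 genotypes ran together across genes, and edgeR called no single gene as responding differently, while DESeq2 called 29. Of 5985 genes called in WT, 5815 (97.2%) changed in the same direction in ARNoC. Both responses called 2282 genes up, where independent lists would share 604.6, and 1819 down, where they would share 482.5. In 5 genes the called directions were opposite. The log2 fold changes had a Pearson correlation of 0.805 and a Spearman correlation of 0.792 across 15261 genes, which are not independent replicates, and the comparisons share no libraries. The Pearson correlation was 0.389 with no filter and 0.856 with at least 50 counts. The slope of the ARNoC on the WT response was 0.919 ± 0.148 (jackknife SE over libraries). The interaction of genotype and treatment gave 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 1307 genes, where chance gives 763. DESeq2 called 29 genes, limma-trend 1 (Gm7714) and limma-voom 0. DESeq2 gave no adjusted p for 2668 genes here, so its count was adjusted over fewer genes than that of edgeR. In simulated data the test recovered 66.7% of 30 genes with a log2 interaction of 1 and 86.7% of 30 with a log2 interaction of 2. These genes had a mean of at least 50 counts, so recovery of tested genes with fewer counts is not known. They were also changed all at once, and the Benjamini-Hochberg threshold loosens as more genes pass. With 0 genes passing in the real data, recovery of a few isolated genes may be lower than these shares.

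Intervals show how large a difference between responses the data leave open. For 5421 of the 7407 genes called in either genotype (73.2%), the 95% limma interval of the interaction lay within a log2 value of -1 to 1, and for 13 it lay beyond. Fkbp5 rose alike, with an interaction of 0.04 and an interval of -0.26 to 0.34. The rise of Odc1 had an interaction of -0.80 (interval -1.18 to -0.47, adjusted p 0.194 by edgeR with Benjamini-Hochberg adjustment), which DESeq2 called. Pbsn had an interval of -1.70 to 2.01, too wide to tell. By camera 18 of 33 lists differed between the responses, 16 higher and 2 lower in ARNoC, although edgeR called 0 of their member genes; adjusted over the list alone it called 3 urothelium markers lower. The myeloid (median 0.89), endothelial (0.78), fibroblast (0.78) and mitosis (0.62) lists were among the higher ones, with camera adjusted p of 1.03e-05, 1.09e-05, 0.000481 and 0.0058. The mitosis call ended without WT vehicle library 5, WT testosterone library 1 or 2, ARNoC vehicle library 5 or ARNoC testosterone library 3 or 4 (0.0589 to 0.368), and the fibroblast call without ARNoC vehicle library 5 (0.0657). All 18 calls ended when the correlation was estimated, with adjusted p = 0.712 with an estimated correlation for each.

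**Figure D3:**
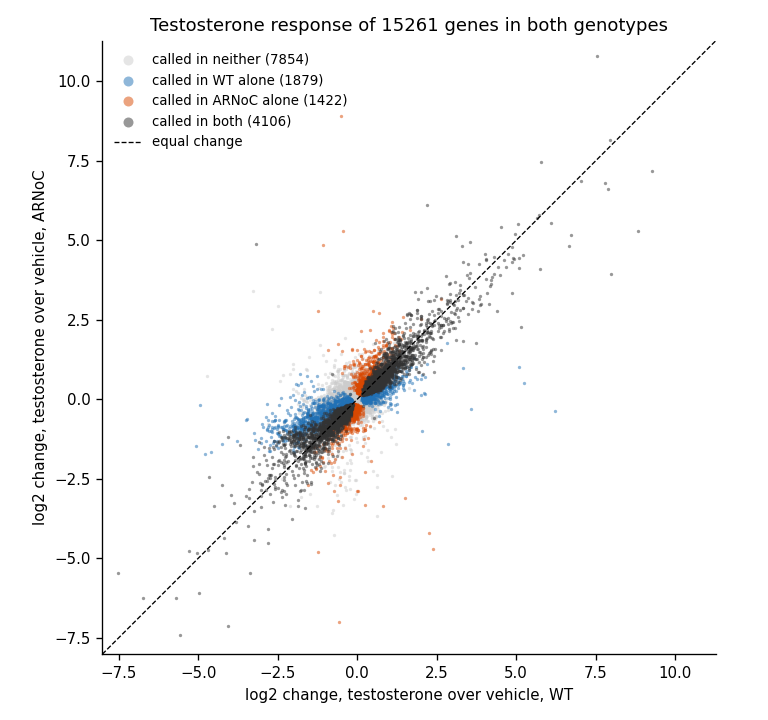
Log2 fold change with testosterone in ARNoC (vertical axis) against that in WT (horizontal axis) for 15261 genes, 1 point per gene, coloured by the test in which the gene was called. Called in both were 4106 genes, in WT alone 1879, in ARNoC alone 1422 and in neither 7854.

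Without added hormone, ARNoC prostates differed from WT in few genes. Zbtb16, a zinc finger transcription factor gene, was 1.35-fold higher in ARNoC (306.8 ± 30.6 against 228.7 ± 22.85, adjusted p 0.0357 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The naming rule took Zbtb16 for the WT response alone, so its place here was chosen outside that rule. Pdzk1, a scaffold gene of membrane transporters (chromosome 3, 96829284 to 96870926), was 2.54-fold higher (480.8 ± 75.2 against 189.2 ± 24.9, adjusted p 0.000241). Hottip, a long noncoding RNA at the end of the Hoxa cluster, was 5.83-fold lower (36.4 ± 19.1 against 209.8 ± 50.1, adjusted p 0.000484). In all 49 genes were called, 26 higher and 23 lower, of which 15 and 15 differed at least 2-fold. Also higher were Gm12873 (5.91-fold), the class I related gene H2-Q10 (5.76-fold), the mucin gene Muc19 (4.83-fold), Atp6v1c2 (2.36-fold) and the transporter gene Slc16a12 (2.28-fold). Also lower were Wscd1 (3.72-fold), the fatty acid binding gene Fabp5 (3.10-fold), the collagen gene Col6a3 (2.48-fold) and Angpt2, a ligand of blood vessel receptors (2.20-fold). Grik2, with fewer counts (5.44 ± 4.31 against 38.6 ± 7.47), was 6.72-fold lower (adjusted p 0.000816). Fkbp5, Pbsn, Odc1, Mki67 and Clu did not pass the test (log2 0.12, 0.68, 0.19, 0.04 and 0.56). Of the 26 higher genes, 22 rose with testosterone in WT and 0 fell, and of the 23 lower genes, 19 fell in WT and 3 rose. These counts share the vehicle libraries of WT with the comparison they describe.

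Of 33 lists 6 were called with vehicle by camera, and each had adjusted p = 0.846 with an estimated correlation. Secretory products were higher in ARNoC (median 0.37, adjusted p 0.00174, 1 of 19 genes higher). Lower were the cholesterol synthesis (-0.13, adjusted p 0.00347), fatty acid synthesis (-0.26, 0.00917), endothelial (-0.53, 0.000207), myeloid (-0.34, 0.00834) and erythroid lists (-1.10, 0.011), in which 0 genes were called, also adjusted over the list alone. In the secretory list 1 gene was called adjusted over the list alone as well. Without ARNoC vehicle library 5 the endothelial, myeloid and erythroid calls ended (camera adjusted p 0.12, 0.735 and 0.112). Without WT vehicle library 1 or 5 those of the fatty acid (0.219 and 0.0785), myeloid (0.174 and 0.542) and erythroid lists (0.0594 and 0.162) ended, and without ARNoC vehicle library 4 that of fatty acid synthesis (0.051). Limits are the spread of the tools and single libraries: DESeq2 called 137 genes and a fit on the 2 vehicle groups alone 19, with the calls of Atp6v1c2, Muc19, Col6a3, Fabp5 and Angpt2 lost in the latter (log2 1.23, 2.26, -1.32, -1.64 and -1.14). With limma-voom those of H2-Q10 (2.46), Atp6v1c2 (1.3) and Muc19 (2.59) ended, and that of Muc19 also with the deposited size factors (2.27), with limma-trend at a pseudocount of 0.5 (2.49) and with a robust fit (2.48). The call of Atp6v1c2 also ended without WT vehicle library 3, 4 or 5 or ARNoC vehicle library 1 or 5 (1.12 to 1.23), and that of Muc19 without any 1 of the WT vehicle libraries or ARNoC vehicle library 1, 3 or 5 (1.93 to 2.46). Without WT vehicle library 4 or ARNoC vehicle library 1 the count was 29, without ARNoC vehicle library 5 it was 31, and Col6a3 was no longer called without ARNoC vehicle library 1 (-1.28) or 5 (-1.22), nor H2-Q10 (2.46), Col6a3 (-1.20) and Muc19 (2.43) without both stroma-poor libraries.

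With testosterone more genes differed between the genotypes. Odc1 was 1.53-fold lower in ARNoC (1073 ± 203 against 1644 ± 88.6, adjusted p 0.00863 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Car2 2.11-fold lower (adjusted p 0.00556). Fkbp5 (log2 difference 0.16, adjusted p 0.508), Pbsn (0.72, adjusted p 0.61) and Clu (0.30, adjusted p 0.639) did not pass the test. Gm7714 was at 1.18 ± 1.43 in ARNoC and 453.3 ± 485 in WT, 351-fold lower, while the vehicle groups had 166.4 ± 45.9 and 671.4 ± 175. Without WT testosterone library 2, which had 1300 against 132.7 to 363.4, it was 186-fold lower, and without ARNoC testosterone library 2 560-fold. The test called 258 genes, 104 higher and 154 lower in ARNoC, of which 27 and 49 differed at least 2-fold. Also lower were the neuronal calcium sensor gene Caln1 (14-fold, or 23.4-fold without ARNoC testosterone library 1), Scgb2b4-ps (11.6-fold), Scgb2b7 (8.95-fold), and the glutamate receptor gene Grik2 (8.51-fold). Also higher were BC051142 (9.95-fold), Gm12873 (8.35-fold), Cacna1i (5.19-fold), Fgl1 (4.26-fold) and H2-Q10 (4.16-fold). Adam7 was 34.5-fold higher, a call that ended with limma-voom (log2 4.96), and the value was 12.9-fold without ARNoC testosterone library 3 and 74.6-fold without WT testosterone library 4. Of the 49 genes called with vehicle, 25 were called here too, all in the same direction, where independent lists would share 0.2 genes in each direction.

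At its preset correlation camera called lists of immune, metabolic and stromal genes different between the genotypes with testosterone. With an estimated correlation 0 of 33 lists were called, and fry called 1. In the interferon and MHC list 3 of 35 genes were higher in ARNoC and 0 lower, also adjusted over the list alone: B2m, H2-K1 and H2-D1, the subunits of class I molecules, named after their values were seen. B2m was 1.54-fold higher (12340 ± 1288 against 8024 ± 1312, adjusted p 0.00517 by edgeR with Benjamini-Hochberg adjustment), H2-K1 1.33-fold and H2-D1 1.22-fold. The calls of H2-K1 and H2-D1 ended in a fit on the 2 testosterone groups alone (log2 0.41 and 0.29) and with no filter (0.41 and 0.30). That of H2-K1 also ended without WT testosterone library 3, 4 or 5 or ARNoC testosterone library 1, 2, 4 or 5 (0.32 to 0.42). That of H2-D1 ended without any 1 of the WT testosterone libraries or ARNoC testosterone library 1, 2, 4 or 5 (0.24 to 0.31). The list median was 0.26 (camera adjusted p 0.000735), and adjusted p = 0.93 with an estimated correlation held for this list and for 11 of the other called lists. Higher were oxidative phosphorylation (median 0.10, camera adjusted p 0.00019), smooth muscle (0.49, 0.000631), S phase (0.33, 0.000735), fibroblast (0.68, 0.000735), myeloid (0.48, 0.00323), mitosis (0.58, 0.00999), secretory (0.60, 0.0151) and regression genes (0.21, 0.0238). The adipocyte list was called higher (adjusted p 0.0213), with a median of 1.03 on the limma scale that camera uses and of 0.02 by edgeR. Lower were urothelium (-0.66, 0.0158) and endoplasmic reticulum genes (-0.08, 0.0178). Glucocorticoid-responsive genes were higher (0.16, camera adjusted p 0.00323), with adjusted p = 0.198 with an estimated correlation. The 1 called fibroblast marker, Col6a3, was lower (log2 -2.28), opposite to its list. In these lists between 0 and 1 gene was called over all genes, and adjusted over the list alone the counts up and down were 5 and 2 of 19 secretory genes, 2 and 0 of 45 oxidative phosphorylation genes, 1 and 1 of 30 regression genes, 3 and 0 of 24 glucocorticoid-responsive genes and 0 and 3 of 5 urothelium markers. The mitosis call ended without WT testosterone library 1, 2 or 5 or ARNoC testosterone library 3 or 4 (camera adjusted p 0.0574 to 0.696), and that of S phase without ARNoC testosterone library 4 (0.367). Those of the endoplasmic reticulum ended without WT testosterone library 2 or 4 or ARNoC testosterone library 1 or 4 (0.0613 to 0.775), of adipocytes without WT testosterone library 2 or 3 or ARNoC testosterone library 3 (0.184 to 0.443), and of secretion without WT testosterone library 4 (0.0713) or ARNoC testosterone library 2 (0.0521). Without WT testosterone library 2 the regression and fibroblast calls ended (0.0824 each), without ARNoC testosterone library 3 the regression (0.132) and myeloid calls (0.066), and without WT testosterone library 5 the urothelium call (0.116).

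The testosterone libraries also differed in makeup. The 10 most abundant genes took 24.0 ± 2.84% of counts in WT and 19.6 ± 1% in ARNoC, a difference of -4.40 (exact permutation p 0.00794, two-sided, the smallest these groups allow; 0.0318 adjusted over 20 tests). Sbp, a secreted spermine-binding protein gene, held 11.8 ± 1.43% of counts in WT and 7.76 ± 0.95% in ARNoC, while its log2 difference of -0.70 did not pass edgeR's test (adjusted p 0.07). It did pass under 9 alternatives, among them DESeq2 (-0.70), total-count scaling (-0.61), the stromal covariate (-0.47) and leaving out WT testosterone library 5 (-0.78). Scaling to the total count gave 335 genes higher and 101 lower in place of 104 and 154. The count of called genes was 498 with DESeq2, 153 without WT testosterone library 3, 157 without WT testosterone library 1, and 170 without ARNoC testosterone library 5. Single calls were lost for Cacna1i without WT testosterone library 1, 3, 4 or 5 (2.22 to 2.40), for Scgb2b4-ps without ARNoC testosterone library 1, 3, 4 or 5 (-3.23 to -3.57), and for Scgb2b7 without WT testosterone library 1, 2 or 4 or any 1 of the ARNoC testosterone libraries (-2.80 to -3.35). With limma-trend the calls of Cacna1i (2.40) and Scgb2b7 (-2.86) ended, and that of Scgb2b7 also with limma-voom (-3.02) and array weights (-2.88).

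Genes at 1 end of the Hoxa cluster on chromosome 6 were lower in ARNoC with both treatments. Named after their values were seen, Hoxa13, a homeobox gene of distal organs (52257694 to 52260880), was 2.07-fold lower with vehicle (adjusted p 0.000241 by edgeR with Benjamini-Hochberg adjustment) and 2.20-fold lower with testosterone (adjusted p 7.9e-05). Its neighbour Hottip (52262775 to 52267603) was 5.83-fold and 6.06-fold lower. The antisense RNA 5730457N03Rik (52308389 to 52314832) was 15.7-fold lower with vehicle and 7.67-fold lower with testosterone (adjusted p 6.08e-05 and 0.00183), or 11.9-fold in the latter without ARNoC testosterone library 4. Evx1 (52313498 to 52318378), which it overlaps, was 5.37-fold lower with vehicle (adjusted p 0.0357) and did not pass the test with testosterone (log2 -2.01, adjusted p 0.151). The strand setting of the counts is not given in the sources used here, so reads of this overlapping pair cannot be told apart. The same holds for Hoxa11 and Hoxa11os, which overlap, and for Gm27817 and Gm27454, which lie within Hoxa11os. The call of Evx1 with vehicle ended with limma-trend (-2.29), with no filter (-2.41), in a fit on the vehicle groups alone (-2.44), without both stroma-poor libraries (-2.48) and without WT vehicle library 1, 3 or 4 or ARNoC vehicle library 1, 2, 3 or 5 (-2.17 to -2.54). Hoxa11 (log2 -0.30 and 0.05), Hoxa10 (-0.26 and -0.30), Hoxa9 (-0.19 and -0.36) and the other tested protein-coding Hoxa genes on that side were not called. The RNAs Hoxa11os (-0.54, adjusted p 0.0335) and Gm27817 (-1.19, adjusted p 0.0373) passed the test with testosterone; with vehicle they differed by -0.52 and -0.39 (adjusted p 0.0891 and 0.824), and Gm27454 beside them passed with neither treatment (-0.84 and -0.58, adjusted p 0.461 and 0.524). Hoxa13 and Hottip also fell with testosterone within each genotype, by log2 -1.85 and -2.61 in WT and -1.94 and -2.67 in ARNoC.

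**Figure D4:**
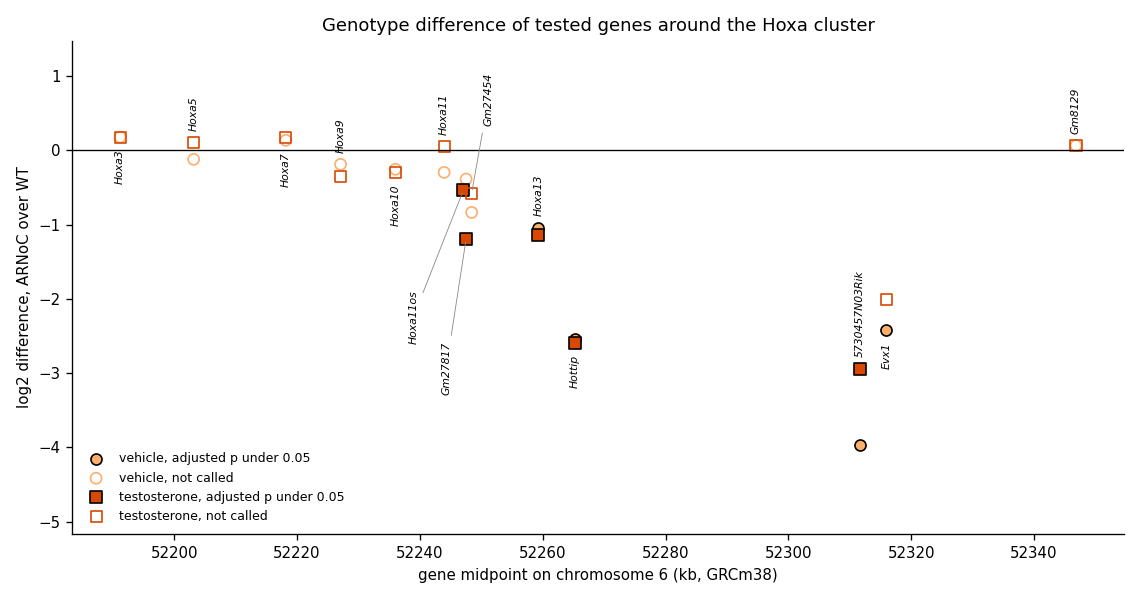
Log2 difference of ARNoC from WT for the tested genes of the Hoxa region, plotted by position on chromosome 6 (mm10), with 1 point per gene for vehicle and 1 for testosterone. Hoxa13, Hottip and 5730457N03Rik lie below 0 with both treatments (-1.05, -2.54 and -3.97 with vehicle), and Hoxa3 to Hoxa11 were not called.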

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

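Among the tests of this part, those of dilution by luminal RNA and of single libraries were chosen after the results were seen. Lower Hoxa genes in ARNoC and falling macrophage markers with testosterone are weighed first, followed by single libraries far from the rest of their group.

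Hoxa13, Hottip and 5730457N03Rik, genes at 1 end of a cluster that sets positional identity, were lower in ARNoC with both treatments. Averaged over treatments, the 6 genes called at this end with either treatment had a median log2 difference of -1.65, in which Gm27454 of the same stretch, not called, has no part. The median was -1.618 with the stromal score as a covariate, which argues against the share of stroma, as this score measures it, as the cause. With the urothelium score it was -1.666. Mean urothelium scores were 8.292 in WT and 8.654 in ARNoC with vehicle, and 7.794 and 7.461 with testosterone. Averaged over treatments the genotypes were thus nearly alike in this score, so the urothelium covariate could hardly move the median and does not decide. A segment of other strain DNA at the cluster stays open, as do an effect of the altered receptor on the region and a different dissection of the tissue, none of which was tested.

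Macrophage and myeloid markers, such as Aif1 and Ctss, fell with testosterone in both genotypes (median -2.07 in WT and -1.20 in ARNoC). More luminal RNA would lower all other cell types alike. The lymphocyte score fell too in WT (-1.69, exact permutation p 0.0371 adjusted over 14 tests) and had a lower mean in ARNoC (-0.89, 0.0888). Fibroblast (-1.15, -0.27), endothelial (-0.95, -0.08), basal (-0.59, -0.37) and adipocyte scores (-2.31, -0.18) had lower means without passing the adjusted test (0.0556 or above). Smooth muscle scores did not fall (0.28, 0.59). Luminal (0.006, -0.073) and proximal luminal scores (-0.054, -0.004) hardly moved. Nerve (-0.296, 0.056), erythroid (-0.834, 0.347), skeletal muscle (0.672, -0.923) and urothelium scores (-0.498, -1.193) did not pass the adjusted test either (0.0888 or above). The myeloid minus the smooth muscle score changed by -2.25 in WT and -1.67 in ARNoC. Its exact permutation p was 0.00794 in each, the smallest 5 against 5 libraries allow, or 0.0371 and 0.0888 adjusted over 14 tests. Smooth muscle was taken as the reference after the scores were seen, and its mean was higher with testosterone. The gap can therefore hold a rise of smooth muscle and does not decide how much of the myeloid fall is dilution. The WT median was -2.22 when libraries were scaled without their 10 largest genes. The main scaling already discounts a few dominant genes, so this setting could hardly have shown a smaller fall and decides nothing. With total-count scaling, which leaves their weight in, the median of all genes was -0.444 in WT and -0.355 in ARNoC. That of the myeloid markers was -2.486 and -1.556. This scaling moves all genes of a library by the same factor (median shift -0.422 in WT and -0.346 in ARNoC), so these values restate the main fit. In that fit the myeloid markers already fell further than the median gene, which argues against abundant secretory genes as the whole cause. The smallest fall without a single library was -1.734 in WT (without vehicle library 5) and -1.005 in ARNoC (without vehicle library 4), which argues against any single library as the whole cause. Fewer macrophages in the gland with testosterone and lower expression of these genes in each macrophage stay open.

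Other ways of splitting the same libraries were counted, 100 for each comparison with the real one included. A count as large as the real one came from 1 of 100 splits, the real one, in WT (5985 genes, highest other 2839), in ARNoC (5528, highest other 1305), between genotypes with vehicle (49, highest other 16) and with testosterone (258, highest other 70). That share is the smallest these splits can give, so chance is an unlikely source of these counts but is not excluded. For the interaction, 100 of 100 regroupings gave at least the real count of 0 genes by edgeR (1307 at an unadjusted p under 0.05; DESeq2 29, limma-trend 1, limma-voom 0), and the highest other was 22; a real count of 0 fixes this outcome, so it decides nothing. A slope as far from 1 as the real 0.919 came from 48 of 100 regroupings, the farthest at 1.4, so chance cannot be excluded for the slope.

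A library lay far from the other 4 of its group in 29 of 324 groups of values, where chance gives about 16.2. In WT with vehicle, library 2 had 76.83 normalized counts of Mthfd2 (others 41.69 to 49.71). Library 3 had 502.9 of Timp4 (350.4 to 370.9) and 3369 of Sat1 (2169 to 2485). Library 1 had 367.8 of Gm7714 (692 to 794.5) and library 4 had 537.3 of Caln1 (217.3 to 266.7). In WT with testosterone, library 2 had 5238 of Clu (3639 to 4070), 1300 of Gm7714 (132.7 to 363.4) and 287.6 of Gm12873 (94.02 to 121.6). Library 3 had 13.96 of Cadps (6.159 to 7.489). Library 5 had 26.63 of Cxcl5 (0 to 7.048) and 19.97 of Clca2 (1.54 to 3.102), and library 4 had 68.13 of Adam7 (1.664 to 14.14).

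In ARNoC with vehicle, library 5, 1 of the stroma-poor libraries, had 14440 normalized counts of Spink3 (others 3122 to 6393) and 100 of Scgb2b7 (0 to 13.93). Library 4 had 541.9 of Gm12873 (1022 to 1204) and 1091 of Hoxa13 (597.4 to 731.6). Library 1 had 1.438 of Adam7 and 2.876 of G6pc2, and library 2 had 1.9 of Mroh4, where the others had 0. In ARNoC with testosterone, library 3 had 2649 of Adam7 (140.1 to 533.8), 864.3 of Lipe (437.8 to 542.4) and 174.5 of P2rx6 (325.2 to 370.1). Library 2 had 166.2 of Fgl1 (52.08 to 72.59), 9489 of Med22 (7795 to 8201) and 13680 of H2-K1 (10790 to 11550). Library 4 had 12 of Hottip (2.341 to 4.252), the largest total, 21.6 in units of 1e+06 counts (11.01 to 12.26), and a size factor of 1.667 (0.8425 to 0.9408). Library 5 had 10.68 of Cadps (1.063 to 3.513).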

How the results depend on the processing

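Among these alternatives limma-trend as first planned, the deposited size factors, leaving out both stroma-poor vehicle libraries, the stromal covariate and fry were chosen after the data were seen. For the named genes, 2607 values under other settings kept their direction and side of the threshold. A further 56 lost a call, 28 gained one and 37 uncalled values changed sign. Leaving out single libraries gave 1807, 65, 6 and 53. Reversed values, both uncalled in the main test, were those of H2-K1 in WT (-0.284) and H2-D1 in ARNoC (-0.207), under total-count scaling. For the lists 935 values were alike in the same sense, 137 lost a call, 30 gained one and 33 changed direction, with 1701, 108, 68 and 103 without single libraries. Total-count scaling gave 10204 genes in WT, 8716 in ARNoC, 436 between genotypes with testosterone and 2 in the interaction, since it follows the share of the most abundant genes. Asking for 2-fold left 1815, 1439, 30 (vehicle) and 76 (testosterone), by construction. Between genotypes with vehicle the count was 19 with the compared groups alone, 158 with array weights, 137 with DESeq2 and 95 with the stromal covariate; with testosterone it was 498 with DESeq2 and 442 with the stromal covariate (269 higher and 173 lower, against 104 and 154). The interaction had 1 gene with limma-trend, with a pseudocount of 0.5 and with a robust fit, 2 with no filter and with array weights, and 29 with DESeq2. With no filter the correlation of responses was 0.389 and the share of bounded genes 66.6%, and with at least 50 counts that share was 83.3%. With an estimated correlation 0 lists were called in any comparison. Fry called 15 lists in the WT response, 17 in the ARNoC response, 0 between genotypes with vehicle, 1 with testosterone and 0 in the interaction; 10 lists were called with vehicle without both stroma-poor libraries and 8 with testosterone under total-count scaling. Without single libraries the counts ran from 29 to 73 with vehicle (lowest without WT vehicle library 4, highest without ARNoC vehicle library 4), 153 to 258 with testosterone and 0 to 2 in the interaction, and the called lists from 5 to 12 with vehicle and 8 to 17 with testosterone. Where no reason is given the cause was not tested. Depth of 8.86 to 21.6 (in 1e+06 counts) limits genes of few counts.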

Other observations

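Of the tests in this part, those of neighbours in the ARNoC libraries, of neighbours on the 5′ side and of a testosterone-like state were chosen after the results were seen. P2rx6, an ATP-gated ion channel gene, and Cyp2b10, a gene of steroid and drug metabolism, were named after their values were seen, since their responses went apart between genotypes. P2rx6 rose with testosterone in WT (665.2 ± 69.96 to 946.1 ± 103 normalized counts, log2 0.52, or 0.09 and not called under total-count scaling) and fell in ARNoC (467.0 ± 55.97 to 308.6 ± 77.2, log2 -0.59). With testosterone it was 3.05-fold lower in ARNoC (adjusted p 1.03e-05 by edgeR with Benjamini-Hochberg adjustment), the smallest adjusted p of that comparison, in 5 of 5 libraries. Its interaction of -1.10 did not pass edgeR's test (adjusted p 0.0903), but did with DESeq2 and without ARNoC testosterone library 3 (-0.96).

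Cyp2b10 rose 4.42-fold with testosterone in WT (211.4 ± 51.4 to 929.6 ± 252) and was not called in ARNoC (417.2 ± 141 to 463.9 ± 125, log2 0.15). Its interaction of -1.99 had an adjusted p of 0.0666 by edgeR with Benjamini-Hochberg adjustment, and passed under 5 alternatives, among them DESeq2 (-1.98), total-count scaling (-1.89) and leaving out ARNoC vehicle library 3 (-2.13). With testosterone it was 2-fold lower in ARNoC (adjusted p 0.0315), a call that ended without WT testosterone library 1, 2 or 4 or ARNoC testosterone library 2, 3 or 4 (-0.85 to -1.05). Marker scores of other tissues varied between libraries of a group, for a reason that was not tested: skeletal muscle scores ran from 2.58 to 9.46 in WT with vehicle and adipocyte scores from 4.14 to 10.5 in WT with testosterone.

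Genes beside strongly induced genes rose with testosterone as well. Abo, Surf6 and Med22 lie side by side on chromosome 2 and rose by log2 6.10, 2.12 and 1.55 in WT and 5.56, 2.07 and 1.67 in ARNoC. Of 97 called genes that rose at least 8-fold in WT, 58 had known coordinates and a mean of at least 50 normalized counts in the higher group. Around these 58, 51 neighbours within 50 kb had a median of 0.30, with 25 called up and 5 down, against -0.01 for random neighbours (95% -0.12 to 0.09), and in ARNoC 0.25 against 0.001; each permutation p was 1e-04, the smallest that 10000 sets can give. Shared local regulation is a candidate explanation: the 25 neighbours on the 5′ side, Surf6 among them, which read-through from the induced gene cannot reach, had a median of 0.30 against 0.01 for random ones (permutation p 0.0021), while for the 3′ side (median 0.44, one-sided permutation p 0.22 against the 5′ side) read-through cannot be told apart from it.

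A further hypothesis is that ARNoC prostates without added hormone may be in a partly testosterone-like state, since Pdzk1 and Zbtb16 were higher with vehicle. Pdzk1 was taken by the naming rule for that comparison, and Zbtb16 was not. Of the 26 genes higher in ARNoC, 20 were called up and 0 down in the ARNoC response, and of the 23 lower genes 16 were called down and 2 up, where the shared ARNoC vehicle libraries work against such overlap. Against it, Fkbp5, Pbsn and Odc1 did not pass the test with vehicle (log2 0.12, 0.68 and 0.19, adjusted p 0.915, 0.913 and 0.808), and Clu, which testosterone lowers, was at 0.56 (adjusted p 0.664). The androgen-responsive, endoplasmic reticulum, stress response and zinc lists, which testosterone raises, were not called with vehicle. Nor were the lymphocyte and basal lists, which it lowers. Leaving out single libraries called the androgen-responsive and endoplasmic reticulum lists higher in 4 and 3 of 10 runs, and the lymphocyte list lower in 6. The lists called with vehicle went both ways. Cholesterol synthesis, which testosterone raises, was called lower (median -0.13). Secretory products, which it raises, were called higher, and myeloid and endothelial markers, which it lowers in WT, lower. Without ARNoC vehicle library 5 the myeloid and endothelial calls ended. Fatty acid synthesis and erythroid markers, also lower, were called in neither testosterone response. All of these camera calls ended with an estimated correlation (adjusted p 0.846 or above). Across all 15261 genes the genotype difference and the testosterone response had a correlation of 0.25, inside the range of relabelled vehicle libraries of -0.357 to 0.357 (exact two-sided permutation p 0.278 over 252 relabellings), so the test does not decide.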
